A study of Mus musculus with 8 samples.

How the data were processed

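Gene expression was measured in the white part of the gastrocnemius, a fast-twitch calf muscle, of 8 mice aged 14 to 16 weeks, 4 of them wild type and 4 homozygous for a mutation of Pus1, on a C57BL/6J background reached by 5 generations of backcrossing. Pus1 encodes pseudouridine synthase 1, an enzyme that converts uridine to pseudouridine in tRNA. Per the labels' protocols, cRNA was made from 200 ng of total RNA of each animal and labelled with Cy3 or Cy5. Each of the 4 arrays carried the RNA of 1 mutant and 1 wild type animal of the same sex and the same individual number, so that 4 pairs resulted, 2 male and 2 female. The mutant was labelled with Cy5 on arrays 1 and 3 and with Cy3 on arrays 2 and 4, so each sex held both dye orientations. All 4 arrays lay on 1 slide and the files gave no other batch.

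The deposited scanner files hold spot intensity values on a linear scale, written per the file headers by Agilent Feature Extraction 10.7.3.1 with no background subtraction in the median spot signal and in the local background signal. The same deposited files hold processed intensity values, which per the file headers were background-subtracted with spatial detrending and dye-normalized within each array. They also hold other values per spot, flags of 0 or 1 that per the file headers mark spots well above background, saturated spots and outlier spots. The authors' deposited table for the whole series holds log2 values, as judged from the values: each probe was centred on a median of 0 over the 8 samples (largest absolute probe median 9.55e-07), all columns had the same mean, column medians lay between −0.02 and 0.03, and differences followed the log2 processed signals with slopes of 0.943 to 1.00 and correlations of 0.973 to 0.987 across probes. Of its 55821 probes, 55681 matched the scanner files, and how it was normalized is not given in the sources used here. It held no columns of samples from outside the series (0 columns).

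Each array had 62976 spots, of which 3671 were controls and 59305 carried 55681 probes. The scanner files pair probes with accessions and not with symbols, so probes were named through RefSeq accessions, without versions, in a gene table of assembly GRCm38.p6; 27656 probes had 1 gene symbol (20972 symbols) and 28025 had none and stayed unnamed. The file headers name another build (mm9), so that table served only for names and for which genes neighbour each other, and no coordinates are given. Between 38.0% and 46.5% of spots were well above background in each sample. Median background was 43.5 to 50 units in Cy3 and 139 to 142.5 units in Cy5, against median spot signals of 75 to 84 and 175 to 198.5 units. Saturated spots numbered 0 to 30 per sample and outlier spots 105 to 198. The number of arrays limits the precision of every value below.

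Background was corrected with normexp (offset 50) on median spot and background signals, log ratios were normalized within each array by loess with control spots and outlier spots at weight 0, and control and outlier spots were then left out. The design written beforehand named mean spot signals; the scanner files used here hold medians, which were used in their place. Saturated spots were kept. Spots of 1 probe were averaged, and probes with a value on all 4 arrays (55591) and well above background in at least 4 of 8 samples were tested: 23098 probes, 15081 of them named (11893 genes) and 8017 unnamed. Where a gene had several probes, the probe with the highest mean intensity stood for it. Each log2 ratio was turned to mutant over wild type and fitted in limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with lmFit and eBayes and a probe-specific dye term; p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. SE is the moderated standard error of that fit, and the pair values are the log2 ratios of the single arrays with no dye correction. The difference between the sexes in the genotype effect was an interaction term in the same kind of fit. The sex difference was fitted on separate channels after Aquantile normalization between arrays with lmscFit and an intraspot correlation of 0.187, with genotype and dye as terms. A probe not well above background in any animal of a group has only a bound there, given as "at least" a fold: the bright group's mean against the mean, per array, of the higher of the lowest signal among probes well above background and the dim probe's own.

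The pairing is physical, since animals with the same number shared an array, and the ratio within the array is the block. Deviations of same-numbered animals from their group means correlated across probes at 0.66, 0.28, 0.06 and 0.64, and the wild type animal closest to the mutant was the same-numbered one in pairs 1 and 4 and not in pairs 2 and 3. Labels name individual animals, so the limma p-values of single probes rest on the spread between animals. Camera with the preset correlation and Fisher's exact test compare genes or probes with one another, so their p-values do not measure that spread. In the sex test sex varies only between arrays, and 1 intraspot correlation of 0.187 stands for all 4 arrays.

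Before the data were examined, 35 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists cover pseudouridine synthases, respiratory complexes I to IV, ATP synthase, mitochondrial DNA-encoded genes, mitochondrial ribosomal proteins, mitochondrial and cytosolic tRNA synthetases, the amino acid and mitochondrial stress response (ATF4), mitochondrial chaperones, biogenesis regulators, the tricarboxylic acid cycle, fatty acid oxidation, glycolysis, slow and fast fibre genes, denervation, regeneration, antioxidant, heme and iron, cytosolic ribosomal proteins, circadian clock, immediate early and interferon genes, markers of blood, leukocytes, fibroblasts, tendon, adipocytes, endothelium, Schwann cells and keratinocytes, and sex-linked genes for checking labels. Lists with at least 4 measured members were tested with camera at a preset correlation of 0.01, adjusted over lists. Named were Pus1, up to 12 genes per direction past the threshold with the largest change, filled up to 5 per direction with the smallest p among genes that moved one way in all 4 pairs, up to 4 members per list past the threshold or otherwise the 2 with the smallest p, up to 5 genes per direction for the sex tests, and up to 6 called genes nearest to Pus1. RIKEN clones, Gm and LOC numbers and unnamed probes were not named, and 2 genes that the rule picks are not reported here. Genes outside this rule are marked as chosen after their values were seen. Genes near Pus1 were compared with all other tested, named probes by Fisher's exact test, two-sided, for windows of 10 Mb and, as alternatives, 5 and 20 Mb. No probe passed the adjusted threshold near Pus1, so the same test at an unadjusted p under 0.01 was added after the data were seen.

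The procedures were tested on simulated data with 200 changed probes among 23098. For the genotype effect 2% of probes changed by a log2 of 0.5 were recovered, 82% at 1, 94% at 1.5 and 98% at 2, with 4.17% false calls. For the difference between the sexes in that effect 0% were recovered at any of these sizes. For the sex difference 6%, 52%, 88% and 92% were recovered. Noise was drawn independently for each probe, and an adjusted threshold is easier to pass where 200 probes truly change. These shares thus do not tell which changes a count of 0 in the real data leaves out. Where no list was shifted but genes within lists were correlated at 0.3, camera with the preset correlation called 7 of 33 simulated lists and camera with an estimated correlation called 0.

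Alternatives were processed signals centred on each median, no background correction, offset 16, scaling between arrays, median centring without loess, no filter or a filter on all 8 samples, outlier spots kept, no dye term, eBayes with trend and robust, array weights, separate channels, no array block, a threshold of 0.1, the authors' deposited values, leaving out each pair, camera with an estimated correlation, fry, and the mean over a gene's probes. When a pair was left out, the genotype and list fits kept the dye term. The pair left alone in its dye orientation then weighed as much as the other remaining pairs together. Such values are thus not plain means of the remaining pairs. Added after the data were seen were a fit with the slow-fibre score of each array as a term (the median log ratio of that list on the array) and lists without genes within 20 Mb of Pus1. Plots were drawn with matplotlib 3.10.9 (Python 3.11.15). Spots without a symbol were tested and counted but not named.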

Results

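RNA from the white part of the gastrocnemius was hybridised on 4 arrays of 2 colours, each holding 1 homozygous Pus1 mutant and 1 wild type mouse of the same sex. The 4 mutant and 4 wild type animals thus formed 4 pairs (pairs 1 and 2 male, pairs 3 and 4 female). Between 38.0% and 46.5% of the spots of a sample were well above background, and 23098 probes of 11893 named genes and of 8017 unnamed sequences were tested. The design asks what changes in fast muscle when pseudouridine synthase 1 is lost, and because both sexes were used it also allows the sexes to be compared.

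Pus1, the targeted gene, was lower in the mutant of every pair. Normalized log2 intensity of its 1 tested probe (chromosome 5) was 8.06, 8.36, 8.15 and 8.29 in wild type animals 1 to 4 and 6.75, 6.91, 6.49 and 6.85 in mutants 1 to 4. The probe was well above background in 4 of 4 wild type animals and in 0 of 4 mutants, so that the level was at least 2.76-fold lower in mutants. The 4 pairs gave log2 ratios of −1.31, −1.45, −1.66 and −1.44, with a fitted mean of −1.46 (SE 0.10, n = 4 pairs). After adjustment over all probes the limma p was 0.0786 (unadjusted p 8.01e-06 in the same limma fit), which missed the threshold of 0.05. The adjusted p was 0.0159 without pair 1, 0.00962 without pair 3 and 0.0288 with no array block, but 0.163 without pair 2 and 0.955 without pair 4. With all 4 pairs it was 0.000146 with median centring in place of loess, 0.00549 with no filter on dim probes, 0.0124 with separate channels and 0.0242 with no dye term. The ratios depend on the floor of the mutant signals, and the log2 ratio was −3.29 in the scanner's processed signals. Which part of the transcript the mutation removes is not given in the sources used here.

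**Figure D1:**
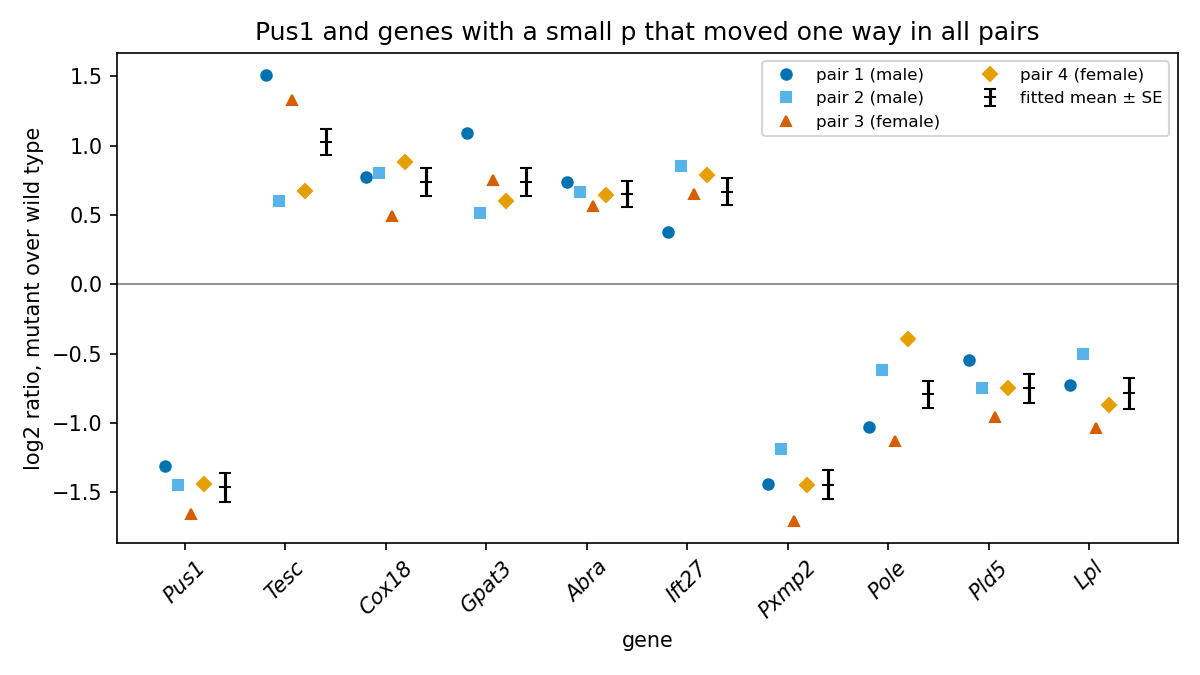
Log2 ratio of mutant over wild type (y axis) for Pus1 and 9 genes with a small p, 5 higher and 4 lower in mutants (x axis), with 1 symbol per pair and the fitted mean ± SE as a black bar. Pus1 lay between −1.66 and −1.31 in the 4 pairs, and the other 9 genes were picked among those that moved one way in all 4 pairs.

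The 6 probes with the smallest p, that of Pus1 included, all lay on chromosome 5, while genes further down the order lay on other chromosomes too. Among genes higher in mutants, the smallest p belonged to Tesc, encoding the calcium-binding protein tescalcin (log2 ratio 1.03, SE 0.09). Next came Cox18, an assembly factor of cytochrome c oxidase (0.74, SE 0.10), and Gpat3, an acyltransferase of glycerolipid synthesis (0.74, SE 0.10). Abra, an actin-binding protein of striated muscle, gave 0.65 (SE 0.09) and Ift27, a component of intraflagellar transport, 0.67 (SE 0.10). Among genes lower in mutants it belonged to Pxmp2, a peroxisomal membrane protein (−1.44, SE 0.10). Other lower values were those of Pole, the catalytic subunit of DNA polymerase epsilon (−0.79, SE 0.10), Pld5, a member of the phospholipase D family (−0.75, SE 0.11), and Lpl, lipoprotein lipase (−0.78, SE 0.11). Each of these 9 genes moved one way in 4 of 4 pairs, which the naming rule demanded, and none passed the threshold. The adjusted p was 0.0786 for Pxmp2, 0.165 for Tesc and 0.596 for the other genes. Tesc, Gpat3, Pxmp2 and Pole lie within 10 Mb of Pus1, so their values cannot be separated from the cluster of changes around it described below. A gene outside these windows can still lie on chromosome 5. That chromosome held 35 probes at an unadjusted p under 0.01, of which 30 lay within 20 Mb of Pus1. Pld5 and Lpl had a further probe each, at −0.43 and −0.48.

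No probe passed an adjusted p of 0.05 in limma (0 of 23098), while 774 probes (3.35%) had an unadjusted p under 0.05 and 158 (0.684%) had one under 0.01. The count was 4 with separate channels fitted by lmscFit, 3 with no array block, 2 with no dye term, 5 with no filter on dim probes and 23 with median centring in place of loess (2 higher, 21 lower). It was 245 without pair 3 (39 higher, 206 lower) and 5 without pair 1. In the fit without pair 3, pair 1 weighed as much as pairs 2 and 4 together, because the dye term was kept. Among the 245 probes, 88 (35.9%) had the same sign in pair 3, against 46.4% of all probes. Over all probes the log2 ratios of different pairs correlated between −0.30 and 0.17 across probes, which are not independent replicates. In all 4 pairs 2294 probes (9.93%) had 1 sign, where independent signs would give 12.5%. The pair values hold no dye correction and the dyes alternate, so a probe's dye effect works against 1 sign. The share to be had without a genotype effect was thus not determined.

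Around Pus1, probes at a small p were frequent in both directions. Within 20 Mb of Pus1, 30 probes of 27 genes had an unadjusted p under 0.01, 15 higher and 15 lower in mutants. All 30 had 1 sign in 4 pairs, which a choice by small p favours. Chosen after their values were seen, examples were Rpap2, a phosphatase of RNA polymerase II (−1.24, SE 0.09), Pebp1, an inhibitor of Raf kinase (−0.58, SE 0.11), and Nos1, neuronal nitric oxide synthase (−0.39, SE 0.09), on the lower side. On the higher side were Ttc28 (0.65, SE 0.10) and Mvk, mevalonate kinase (0.47, SE 0.09). Further probes of Rpap2 gave −0.24 and −0.32, and a further probe of Pebp1 gave 0.15, so that probes of 1 gene differed in size or sign.

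The mice had been backcrossed for 5 generations, so the region around the targeted gene was set apart in advance. Within 10 Mb, 17 of 169 probes (10.1%) had an unadjusted p under 0.01, against 102 of 14911 probes elsewhere (0.684%, odds ratio 16.2, Fisher's exact p = 1.87e-14). Within 20 Mb it was 30 of 349 (8.60%) against 89 of 14731 (0.604%, odds ratio 15.5, Fisher's exact p = 4.90e-23). The odds ratio within 10 Mb was 4.97 without pair 1, 7.50 without pair 2 and 3.40 without pair 3. At the adjusted threshold the count near Pus1 was 0 in limma (Fisher's exact p = 1), and it was 2 without pair 1, 6 without pair 3, 2 with separate channels and 2 with no array block. Over all chromosomes tested in the same way, chromosome 5 had 35 of 927 probes (3.78%, adjusted Fisher's exact p = 4.87e-14) and chromosome 15 had 12 of 574 (2.09%, adjusted Fisher's exact p = 0.0193), the latter in Abra, Ift27, Mb, Ppara and 6 further genes. Clustering of these 10 genes along chromosome 15 was not shown. Their mean distance was 18.7 Mb, against 28.2 Mb for random genes of it (permutation p = 0.142, a test added after the data were seen).

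**Figure D2:**
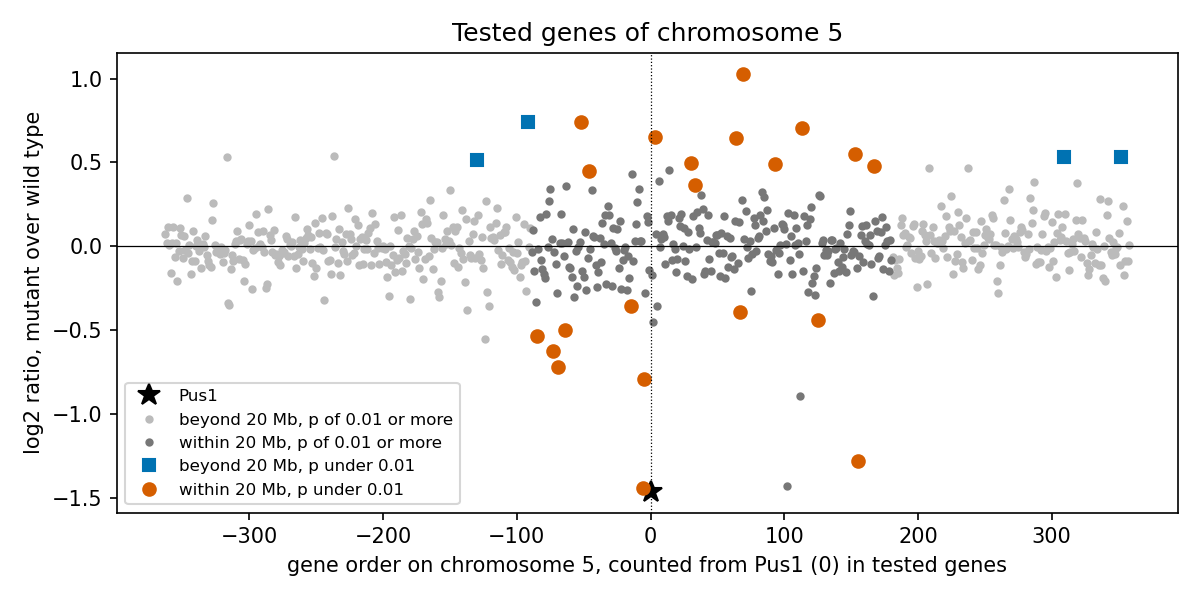
Log2 ratio of mutant over wild type (y axis) for the brightest probe of each tested gene of chromosome 5, in gene order from Pus1 (x axis, 0 at Pus1, star). Large orange circles are genes within 20 Mb at an unadjusted p under 0.01, blue squares are genes beyond 20 Mb at that p, and small grey points are all others. Tesc stood highest at 1.03 and Pxmp2 lay beside Pus1 at −1.44.

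Of 33 gene lists tested with camera at the preset correlation, 17 passed an adjusted p of 0.05, 10 lower and 7 higher in mutants. With an estimated correlation 0 passed (adjusted p = 0.682 with an estimated correlation for each of the 17), and fry, which asks whether a list's genes move on balance one way, called 1 list (2 in either direction). No member of any list passed the threshold over all probes, so values of members below are not calls. The count was 10 lists without pair 3 and 6 without pair 4.

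The genes of slow and oxidative fibres, the minority fibre type in this part of the muscle, had the lowest median of all lists. All 21 measured members lay below wild type in the fitted mean (median log2 ratio −0.92, camera adjusted p = 2.24e-08, adjusted p = 0.682 with an estimated correlation), with 0 past the threshold over all probes and 0 adjusted over the list alone. Myl3, the slow ventricular myosin light chain, gave −1.68 (SE 0.41) and Mb, myoglobin, −0.98 (SE 0.20). Pair medians were −1.47, 0.47, −0.79 and −0.78, so 3 of 4 pairs were lower. The median of the list was −0.0056 without pair 4 (adjusted p 0.0249) and −1.38 without pair 2. In the fit without pair 4, pair 2 weighed as much as pairs 1 and 3 together, because the dye term was kept. Medians of blood (0.75, −0.62, 0.87 and 1.35) and fibroblast markers (0.90, −0.31, 0.15 and 0.47) had the opposite sign in each pair. Levels also spread within groups: Myh7, the slow myosin heavy chain, chosen after its values were seen, had log2 intensity 11.43 ± 3.21 in wild type and 9.70 ± 1.98 in mutants (SD, n = 4 each). The fast and glycolytic fibre list did not pass (21 genes, median 0.02, mean −0.03, camera direction higher, adjusted p = 0.978). Of its members Myh1, the fast 2X myosin heavy chain, gave −1.29 (SE 0.25) and passed when adjusted over the list alone (1 gene), while Myoz3, a Z-disc protein, gave −0.30 (SE 0.10, −0.02 by a further probe).

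**Figure D3:**
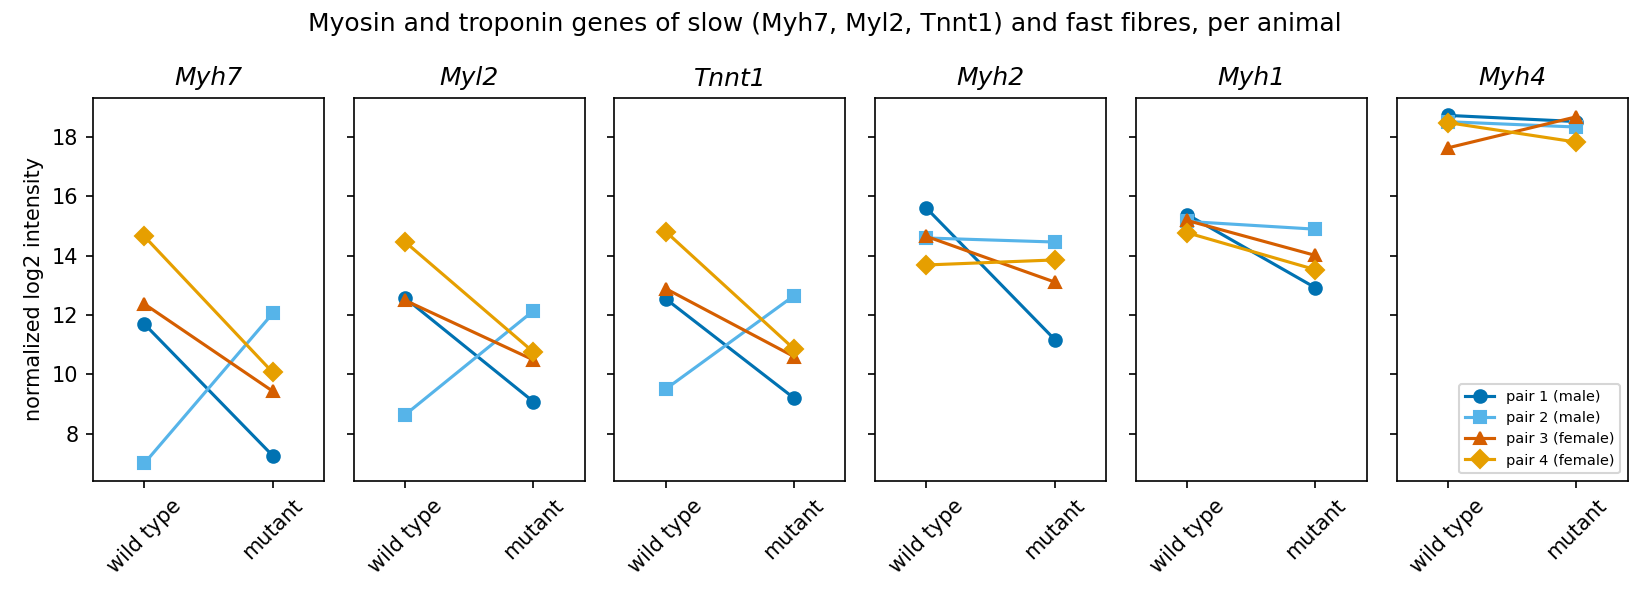
Normalized log2 intensity (y axis) of 3 slow-fibre genes (Myh7, Myl2, Tnnt1) and 3 fast myosin heavy chains (Myh2, Myh1, Myh4) in wild type and mutant animals (x axis), with lines joining the 2 animals of a pair. Pair 2 ran opposite to the other pairs for Myh7, Myl2 and Tnnt1, and Myh1 was lower in the mutant of all 4 pairs. Myl2 lies within 20 Mb of Pus1.

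Nuclear genes of the respiratory chain lay slightly lower in mutants. Camera gave lower lists for complex I (36 genes, median −0.07, adjusted p = 0.00502), complex II (4 genes, −0.17, 0.0238), complex III (10 genes, −0.12, 0.00411), complex IV (15 genes, −0.09, 0.0136) and ATP synthase (16 genes, −0.10, 0.00244), each with adjusted p = 0.682 with an estimated correlation. Medians were lower in 3 of 4 pairs for each, pair 1 being higher for all but complex II, where pair 2 was. Counts past the threshold were 0 over all probes and 0 adjusted over the list alone for each of these lists. Examples were Ndufb10 (−0.20, SE 0.09) and Ndufs1 (−0.19, SE 0.10) of complex I, Sdhb (−0.25, SE 0.12, −0.14 by a further probe) and Sdha (−0.19, SE 0.10) of complex II. Others were Uqcrc2 (−0.19, SE 0.10) and Uqcrq (−0.18, SE 0.10) of complex III, Cox7a2l (−0.19, SE 0.09) and Cox6a1 (−0.17, SE 0.11) of complex IV, and Atp5a1 (−0.30, SE 0.09) and Atp5g3 (−0.29, SE 0.11) of ATP synthase. Cox6a1 lies within 20 Mb of Pus1. All 5 calls ended without pair 3 (adjusted p of 0.754, 0.462, 0.901, 0.901 and 0.901 in that order) and without pair 4 (0.0685, 0.263, 0.0918, 0.0820 and 0.0576). Without pair 1 the medians were −0.13, −0.21, −0.17 and −0.22 for complexes I, III and IV and ATP synthase, and without pair 3 they were −0.0122, −0.0886, −0.0477, 0.0192 and 0.0057 for complexes I to IV and ATP synthase. In the fit without pair 3, pair 1 weighed as much as pairs 2 and 4 together. The median of the slow-fibre list was −1.47, 0.47, −0.79 and −0.78 in pairs 1 to 4, opposite in sign to complexes I, III and IV and ATP synthase in pairs 1 and 2. Of the 15 genes encoded by mitochondrial DNA, 0 were measured.

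Genes of mitochondrial fuel use lay lower too. In the tricarboxylic acid cycle 18 of 19 genes lay below wild type (median −0.16, lower in 3 of 4 pairs, camera adjusted p = 4.74e-06, adjusted p = 0.682 with an estimated correlation). Members included the mitochondrial isocitrate dehydrogenase Idh2 (−0.54, SE 0.15) and malate dehydrogenase Mdh2 (−0.23, SE 0.09). Fatty acid uptake and oxidation was lower (30 genes, median −0.10, 3 of 4 pairs, camera adjusted p = 0.00386, adjusted p = 0.682 with an estimated correlation). Its median was −0.124, −0.137, −0.0567 and −0.0495 without pair 1, 2, 3 and 4. Lpl passed when adjusted over the list alone (1 gene, −0.78), and the thiolase Acaa2 gave −0.35 (SE 0.11). Not all members were lower, as 2 chosen after their values were seen show. Mean log2 intensity of Pdk4 was 12.66 ± 0.65 in wild type and 13.58 ± 0.92 in mutants (SD, n = 4 each). For Angptl4 it was 8.09 ± 0.51 and 8.73 ± 1.38. Neither was higher in the mutant of every pair. Regulators of mitochondrial biogenesis were lower (21 genes, median −0.05, 4 of 4 pairs, camera adjusted p = 0.0120, adjusted p = 0.682 with an estimated correlation), and the nuclear receptors Ppara (−0.59, SE 0.10) and Esrrb (−0.49, SE 0.10) passed when adjusted over the list alone (2 genes). Other Ppara probes ranged from −0.70 to −0.08. The last 2 calls ended without pair 3 (adjusted p 0.754 and 0.374) and without pair 4 (0.549 and 0.0576), and with no array block the biogenesis list missed the threshold (0.0527). The slow-fibre median was −0.92 beside them. Glycolysis and glycogen metabolism did not pass (38 genes, median −0.01, adjusted p = 0.135, 0 adjusted over the list alone). Ldhb, the lactate dehydrogenase subunit of oxidative tissue, gave −1.60 (SE 0.29) and hexokinase 2 (Hk2) −0.36 (SE 0.10).

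Among genes of tRNA modification and translation, the pseudouridine synthase list was lower (12 genes, median −0.05, 3 of 4 pairs, camera adjusted p = 0.0344, adjusted p = 0.682 with an estimated correlation). Pus1 was the 1 member that passed when adjusted over the list alone. Trub2, a mitochondrial pseudouridine synthase, gave −0.16 (SE 0.10, 0.03 by a further probe). The list's call ended without pair 3 (adjusted p 0.356), without pair 4 (0.116) and without Pus1 and the genes within 20 Mb of it (0.325). The list median was −0.0956 without pair 2 and −0.0274 without pair 4. Cytosolic ribosomal proteins were higher (70 genes, median 0.08, 3 of 4 pairs, camera adjusted p = 0.000849, adjusted p = 0.682 with an estimated correlation), with Rpl3 at 0.37 (SE 0.11) and Rps27 at 0.27 (SE 0.11). Without pair 1 the median of the ribosomal list was 0.0296 (camera adjusted p 0.516), and without pair 3 it was 0.120. With median centring in place of loess the median was −0.01. Mitochondrial ribosomal proteins (75 genes, median 0.01, adjusted p = 0.730), mitochondrial tRNA synthetases and tRNA modification (26, −0.03, 0.408) and cytosolic tRNA synthetases (19, 0.02, 0.439) did not pass. Members with the smallest p in these lists were Mrps10 (0.21, SE 0.09) and Mrpl47 (−0.19, SE 0.10, −0.02 by a further probe), Rars2 (−0.17, SE 0.09) and Hars2 (−0.14, SE 0.09), and Dars (0.28, SE 0.09) and Nars (0.13, SE 0.11). All of these lists, other than the first, had 0 members adjusted over the list alone.

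Genes of the amino acid and mitochondrial stress response, many of them targets of the transcription factor ATF4, lay higher in mutants by a small amount. Of 24 measured members 17 lay above wild type (median 0.10, 4 of 4 pair medians higher, at 0.12, 0.12, 0.06 and 0.07, camera adjusted p = 0.00502, fry adjusted p = 0.0145, adjusted p = 0.682 with an estimated correlation), with 0 adjusted over the list alone. Psph, the last enzyme of serine synthesis, gave 0.48 (SE 0.10) and lies within 20 Mb of Pus1, and the transcription factor Atf5 gave 0.34 (SE 0.10). The camera call ended without pair 1 (adjusted p 0.0534) and without pair 3 (0.0561). Lists of mitochondrial chaperones and proteases (17 genes, median −0.02, adjusted p = 0.144), antioxidant and NRF2 targets (27, 0.04, 0.408) and heme, iron-sulphur and iron handling (26, median −0.02, mean 0.02, camera direction lower, 0.968) did not pass, each with 0 adjusted over the list alone. Their members with the smallest p were the mitochondrial chaperone Dnaja3 (−0.18, SE 0.09) and protease Afg3l2 (−0.18, SE 0.09). Others were glutathione S-transferase Gstm1 (−0.24, SE 0.11) and mitochondrial superoxide dismutase Sod2 (−0.18, SE 0.09), and the heme synthesis genes Alas1 (−0.22, SE 0.09, −0.02 by a further probe) and Alas2 (0.64, SE 0.32), the latter also an erythroid transcript.

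Of 8 lists of markers of other cell types, 4 passed camera at the preset correlation, all higher in mutants, and 0 passed with an estimated correlation. Blood (erythroid) transcripts were higher (10 genes, median 0.58, 3 of 4 pairs, camera adjusted p = 0.00386, adjusted p = 0.682 with an estimated correlation), with globin Hba-a2 at 0.62 (SE 0.28). Also higher were leukocyte and macrophage markers (18 genes, 0.19, 2 of 4 pairs, 0.00386, adjusted p = 0.682 with an estimated correlation), with complement C1qb at 0.36 (SE 0.19) and lysozyme Lyz1 at 0.54 (SE 0.35). Fibroblast and matrix markers were higher (23 genes, 0.26, 3 of 4 pairs, 1.30e-06, adjusted p = 0.682 with an estimated correlation), with Sparc at 0.45 (SE 0.09) and collagen Col1a1 at 0.78 (SE 0.22). Higher too were Schwann cell and nerve markers (11 genes, 0.10, 3 of 4 pairs, 0.0366, adjusted p = 0.682 with an estimated correlation), with myelin genes Pmp22 at 0.42 (SE 0.16) and Mal at 0.43 (SE 0.22). In each of these 4 lists 0 members passed when adjusted over the list alone. Pair medians ran 0.75, −0.62, 0.87 and 1.35 for blood, 0.91, −0.33, −0.12 and 0.34 for leukocytes, 0.90, −0.31, 0.15 and 0.47 for fibroblasts and 0.08, 0.07, 0.68 and −0.19 for Schwann cells. Without 1 pair, blood missed the threshold without pair 3 (adjusted p 0.0628) and pair 4 (0.845), leukocytes without pair 1 (0.325) and pair 4 (0.343), fibroblasts without pair 1 (0.0593), and Schwann cells without pair 2 (0.344) and pair 3 (0.995). In the fit without pair 4, pair 2 weighed as much as pairs 1 and 3 together. Without pair 4 the medians were 0.0192 for blood, 0.0239 for leukocytes and 0.0626 for fibroblasts, and without pair 2 they were 1.07, 0.363 and 0.446. Without pair 3 they were 0.493 for leukocytes, 0.483 for fibroblasts and −0.0103 for Schwann cells, and without pair 1 they were −0.06, 0.05 and 0.25. With the slow-fibre score of each array as a term, a fit added after the data were seen, they were −0.23 for blood, −0.31 for leukocytes and −0.21 for fibroblasts. No cause is read from that fit, since 4 arrays leave little spread beside its terms.

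Tendon (8 genes, median −0.03, adjusted p = 0.720), adipocyte (14, 0.11, 0.0876), endothelial and mural (20, median −0.01, mean 0.01, camera direction higher, 0.892) and keratinocyte markers (4, −0.07, 0.112) did not pass, with 0 adjusted over the list alone in each. Their members with the smallest p were Kera (0.41, SE 0.17) and Comp (−0.19, SE 0.10) of tendon, Fabp4 (0.26, SE 0.09) and Scd1 (0.55, SE 0.27) of adipocytes. Further members were Pdgfrb (0.21, SE 0.11) of mural cells and Flt1 (−0.19, SE 0.13) of endothelium, and Perp (−0.33, SE 0.11) and Krt10 (−0.11, SE 0.10) of keratinocytes.

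**Figure D4:**
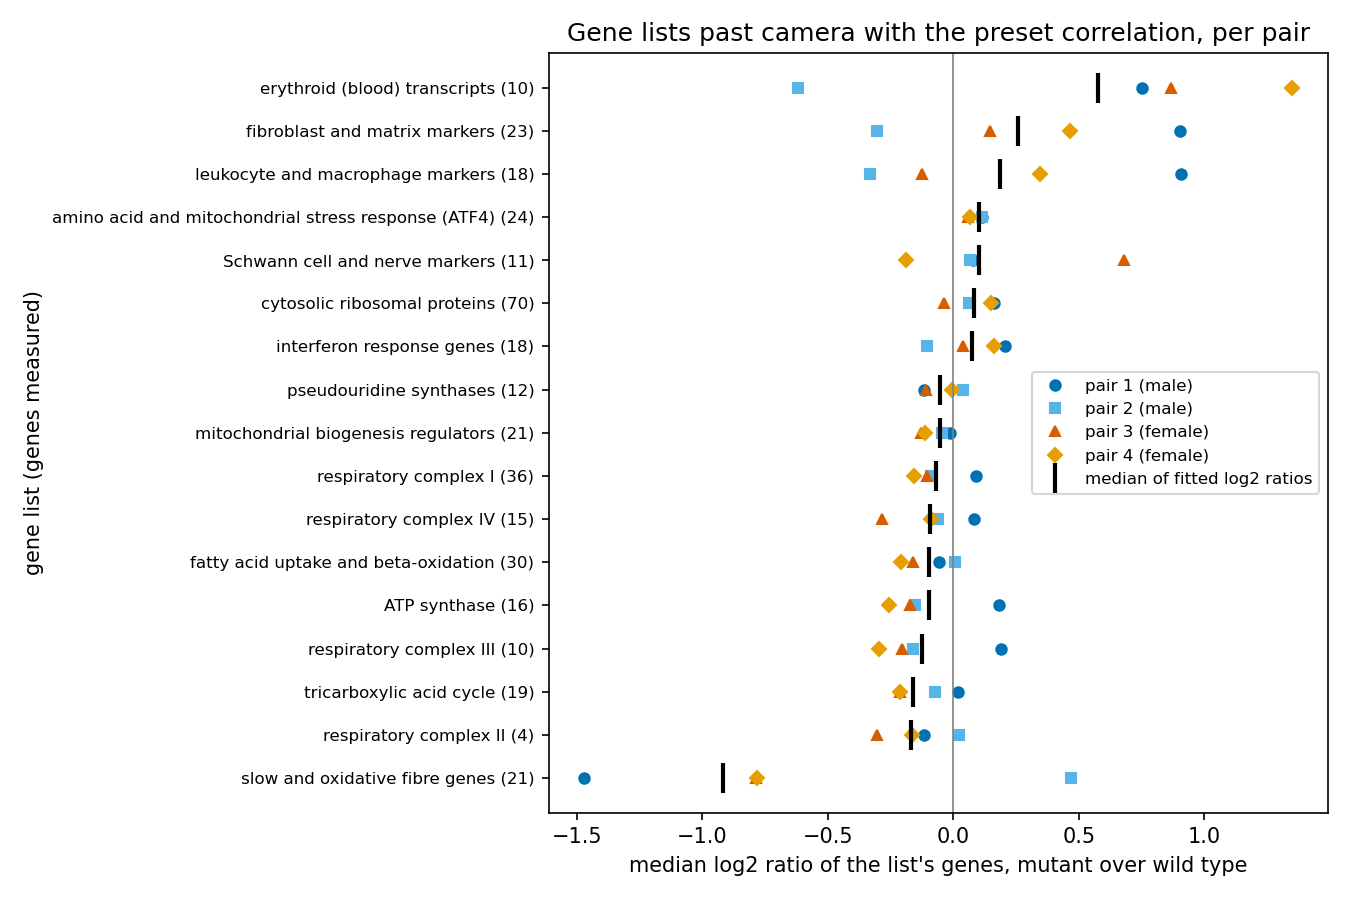
Median log2 ratio of mutant over wild type (x axis) of the 17 gene lists past camera with the preset correlation (y axis, genes measured in brackets), with 1 symbol per pair and a black bar for the median of the fitted values. The slow-fibre list runs from −1.47 in pair 1 to 0.47 in pair 2, and the blood list from −0.62 in pair 2 to 1.35 in pair 4.

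Denervation and atrophy genes did not pass (22 genes, median −0.04, mean 0.04, camera direction lower, adjusted p = 0.720), and neither did regeneration and embryonic myosin genes (12, median 0.01, 0.706), with 0 adjusted over the list alone in both. The cell cycle inhibitor Cdkn1a gave 0.48 (SE 0.13), the ubiquitin ligase Fbxo32 −0.57 (SE 0.18), cardiac actin Actc1 0.88 (SE 0.26) and Mest 0.25 (SE 0.14). Interferon response genes were higher by camera (18 genes, median 0.07, 3 of 4 pairs, adjusted p = 0.0327, adjusted p = 0.682 with an estimated correlation), with Oas2 at 0.32 (SE 0.11) and Oasl2 at 0.31 (SE 0.15) and 0 adjusted over the list alone. Of the 18 interferon genes 3 lie within 20 Mb of Pus1, Oas2 and Oasl2 among them, and without linked genes the camera adjusted p was 0.268. The interferon call also ended without pair 1 (0.337) and pair 4 (0.642, median 0.04), and the median was −0.051 with the slow-fibre score as a term. Leukocyte markers, with medians of 0.91, −0.33, −0.12 and 0.34 in pairs 1 to 4, had the sign of the interferon list (0.21, −0.11, 0.04 and 0.16) in all but pair 3. Circadian clock genes (17, median −0.02, adjusted p = 0.0639) and immediate early genes (15, 0.08, 0.197) did not pass, with 0 adjusted over the list alone. Per1 gave −0.46 (SE 0.16), Tef −0.31 (SE 0.15), Egr1 0.58 (SE 0.18) and Klf4 −0.22 (SE 0.09).

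Whether the mutation acted differently in males and females was asked with 2 pairs of each sex. Pus1 was lower in the mutant of both male and both female pairs, and its size was not compared between the sexes because 0 of 4 mutants were well above background. No probe passed in limma (0 of 23098, smallest adjusted p 0.656), with 506 probes at an unadjusted p under 0.05. On simulated data this test recovered 0% of changed probes at any size tried, so a count of 0 says little. The count was 445 without pair 4 and 7 without pair 3, each fitted with no dye term since 3 arrays leave no spread to estimate with it. It was 38 with no filter on dim probes and 22 with median centring in place of loess.

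Female and male muscle differed in 319 probes (lmscFit in limma, adjusted p under 0.05, n = 4 animals of each sex), 119 higher and 200 lower in females. The count was 47 with no normalization between arrays (9 higher, 38 lower), 850 with no array block (377 higher, 473 lower) and 554 with no filter on dim probes. Of the 319 probes 93 were unnamed, and the others belonged to 203 named genes of which 195 are autosomal, 6 on X and 2 on Y. The Y-linked genes Eif2s3y, a translation factor subunit, and Ddx3y, an RNA helicase, were at least 32.1-fold and at least 16.9-fold higher in males. Also higher in males were Amd2, an enzyme of polyamine synthesis (log2 difference of females minus males −2.57, SE 0.15, adjusted p = 0.000381), Tmem37, a membrane protein (−2.34, SE 0.18, 0.00211), and Crip3, a LIM domain protein (−2.28, SE 0.38, 0.0376). Females had higher Lrfn4, a leucine-rich adhesion protein (2.52, SE 0.31, 0.0127), Pla2g5, a secreted phospholipase (2.11, SE 0.33, 0.0308), and the major urinary protein genes Mup19 (2.32, SE 0.34, 0.0244), Mup18 (2.26, SE 0.29, 0.0166) and Mup17 (2.01, SE 0.32, 0.0319). These are near-identical copies, so that which copy was measured is uncertain.

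Transcripts of the sex chromosomes separated the 8 animals by labelled sex. Eif2s3y lay at log2 intensity 11.40 to 11.56 in males and 6.00 to 6.36 in females, and Ddx3y at 10.37 to 10.72 and 5.98 to 6.61, with 0 of 4 females well above background for either. Xist, the RNA of the inactive X chromosome, lay at 7.94 to 8.36 in females and 6.12 to 7.30 in males (log2 difference 1.42, SE 0.26) and missed the adjusted threshold. Uty and Kdm5d, also on Y, were too dim to be tested. Sex varied only between arrays, and the count was 247, 54, 32 and 16 without pair 1, 2, 3 and 4, each with the intraspot correlation of all 4 arrays. Eif2s3y, Ddx3y and Amd2 passed in each of these, while without pair 4 the adjusted p was 0.382 for Lrfn4, 0.207 for Mup19, 0.211 for Mup18, 0.177 for Mup17, 0.0838 for Pla2g5, 0.0589 for Tmem37 and 0.517 for Crip3. Without pair 3 it was 0.116 for Mup19, 0.110 for Mup18, 0.123 for Mup17, 0.124 for Pla2g5, 0.0550 for Tmem37 and 0.143 for Crip3. Without pair 2 it was 0.0777 for Lrfn4 and 0.0505 for Mup19, and without pair 1 it was 0.0785 for Pla2g5, 0.0602 for Mup17 and 0.00377 for Xist, which then passed.

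**Figure D5:**
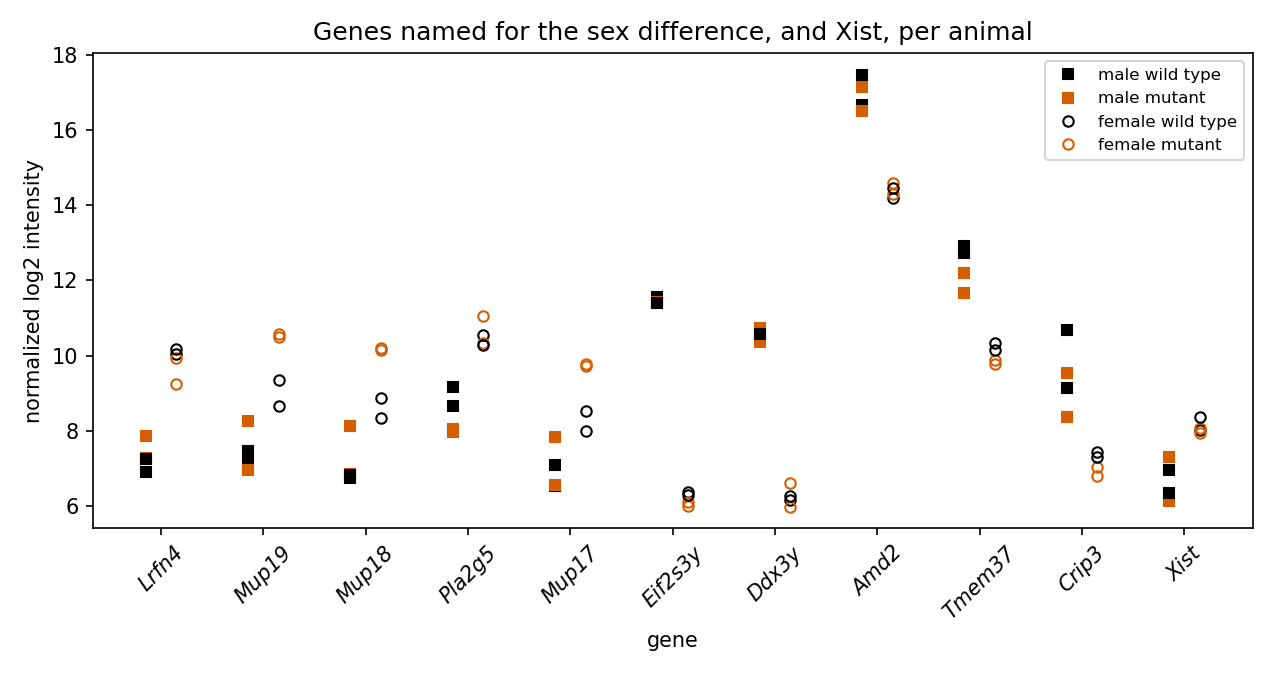
Normalized log2 intensity (y axis) of the 5 genes per direction picked by the naming rule for the sex difference and of Xist (x axis) in each of the 8 animals, with squares for males, open circles for females, black for wild type and orange for mutants. Eif2s3y lies at 11.40 to 11.56 in males and 6.00 to 6.36 in females, and Mup17, Mup18 and Mup19 lie higher in the female mutants than in the female wild type animals.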

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

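The tests of the cluster around Pus1, of the slow-fibre genes, of the stress response list without linked genes and of regrouped arrays were chosen only after the result was seen.

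Genes around Pus1 differed in both directions in mutants. Loss of Pus1 acting on genes wherever they lie would give no excess near the gene, and the odds ratio of an unadjusted p under 0.01 within 20 Mb was 15.5 (Fisher's exact p = 4.90e-23). That excess is the pattern itself, known before the question was asked, so it is no separate test of this explanation. A segment of the donor strain kept around Pus1 after 5 generations of backcrossing is a candidate explanation that stays open: the odds ratio from 5 to 20 Mb was 14.7, but it follows from the counts that prompted the idea and is no separate test. A mismatch under the probe in donor sequence lowers signal, and the 15 probes that were higher in mutants argue against it for their part. Their count was also known before this was asked. For the lower probes it cannot be told apart from lower expression, since only 7 of 15 genes had a further probe, of which 5 were lower and 2 had an unadjusted p under 0.05 (Rpap2 and Septin11).

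Slow and oxidative fibre genes lay lower in the mutants of 3 of 4 pairs, and the medians of blood and fibroblast markers had the opposite sign in each pair. An unequal share of slow-fibre muscle between the pieces of tissue is a candidate explanation: a score over these genes ranged over 1.05 on the log2 scale among the 4 wild type animals alone (−0.22 to 0.83), against a difference of −0.78 between the groups. A range of 4 values easily exceeds a difference of means, so this is a weak test. Spread among wild type animals also does not tell unequal pieces from other differences between animals. Whether the genotype lowers these genes stays open, since the exact two-sided sign-flip p over the 4 pair medians was 0.25 and the smallest that 4 pairs allow is 0.125.

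Stress response genes under ATF4 lay higher in the mutants of all 4 pairs, but the camera call was lost with an estimated correlation (adjusted p = 0.682 with an estimated correlation), without pair 1 (0.0534) and without pair 3 (0.0561). Linked genes within 20 Mb of Pus1 did not account for all of it: without Psph the adjusted fry p over the remaining 23 genes was 0.00557, while the median log2 ratio went from 0.10 to 0.06. No other explanation was tested.

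Some single pairs lay far from the other 3, in 5 of 108 sets of 4 values examined, and chance gives about 1 in 20. The log2 ratio of Ndufs1 was −0.40 in pair 3 and −0.13 to −0.10 in the other pairs. For Scd1 pair 2 gave −0.69 and the other pairs 0.88 to 1.04. The median of the cytosolic tRNA synthetases was −0.19 in pair 1 and 0.05 to 0.08 in the others. Fast-fibre genes had a median of 0.48 in pair 3 and −0.18 to −0.07 in the others. Denervation and atrophy genes had a median of −0.15 in pair 1 and −0.01 to 0.01 in the others.

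Arrays were also regrouped by exchanging mutant and wild type within arrays. The genotype count was 0, so that every assignment (7 of 7) gives as many whatever the data, and this tests nothing. The highest of the other assignments gave 11 probes, with 1 array turned. For gene lists the count was 17 and the highest other was 16, with 1 of 7 giving as many. For the sexes it was 319 and the highest other split gave 0, with 1 of 3 giving as many. The splits of lists and sexes are too few for a share under 0.05.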

How the results depend on the processing

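The fit with the slow-fibre score as a term, the lists without genes near Pus1 and the tests near Pus1 at an unadjusted p under 0.01 were chosen only after the result was seen. Of 1478 values of named genes in the genotype comparison 1439 kept their direction and side of the threshold, 33 passed and 6 turned, and of 408 values of called lists 326 kept theirs, 74 missed the threshold and 8 turned. No named gene passed in the main genotype fit, so keeping its side meant staying uncalled. These genes were picked by small p, which favours a kept direction, so the first share is no measure of robustness. Where a cause is not named, the cause was not tested. Signal over background limits all values, since 38.0% to 46.5% of spots per sample were well above background.

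The genotype count of 0 became 23 with median centring (2 higher, 21 lower), 5 with no filter on dim probes, 2 with no dye term, 3 with no replicate block, 4 with separate channels and 3 at an adjusted p under 0.10, and lay between 0 and 245 when 1 pair was left out. The log2 ratio of Pus1 passed the threshold at −1.54 with median centring, and at −1.46 with no filter, no dye term, no replicate block, separate channels and an adjusted p under 0.10. Its adjusted p ranged from 0.000146 to 1.00 over all alternatives, and leaving out 1 pair gave −1.55 to −1.38. When all 8 samples had to be well above background Pus1 had no value. Within 10 Mb of Pus1 the count of 0 became 4, 3, 1, 2, 2 and 2 in the same order of settings, and 0 to 6 with 1 pair left out. At an unadjusted p under 0.01 the odds ratio lay between 3.40 and 37.3 in 21 alternatives.

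The count of 17 lists became 0 with camera with an estimated correlation and 1 with fry, and was 6 to 18 with 1 pair left out. The genotype by sex count of 0 became 22 with median centring and 38 with no filter, and 0 to 445 with 1 pair left out. The sex count of 319 became 554 with no filter, 850 with no replicate block, 47 with no normalization between arrays (9 higher, 38 lower in females, against 119 and 200) and 1548 at an adjusted p under 0.10, and 16 to 247 with 1 pair left out. With no replicate block 17 lists passed, 8 higher and 9 lower against 7 and 10, and of the lists called with it the biogenesis regulators missed the threshold (median −0.052, adjusted p 0.0527). The genotype by sex comparison was not run without the block.

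With the slow-fibre score as a term, log2 ratios turned to −0.092 for Mest, −0.21 for Alas2, −0.13 for C1qb, −0.41 for Lyz1, −0.16 for Scd1 and 0.044 for Flt1, and list medians to 0.12 for slow fibre, −0.051 for interferon, −0.23 for erythroid, −0.31 for leukocyte and −0.21 for fibroblast genes.

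Leaving out 1 pair gave list medians of −0.129 to −0.0122 for complex I, −0.167 to 0.0192 for complex IV and −0.0633 to 0.493 for leukocyte markers. The direction turned without pair 3 for both complexes, in the test for complex I, and without pair 1 for leukocyte markers. Without pair 3 the medians of ATP synthase (0.0057) and Schwann cell markers (−0.0103) also changed sign. In these fits the pair left alone in its dye orientation weighed as much as the other remaining pairs together. A turn thus need not come from the pair left out.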

Other observations

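The genes of this paragraph and the next were chosen after their values were seen. Several enzymes and signalling genes outside those named above differed between the sexes (log2 difference of females minus males, lmscFit in limma, n = 4 animals of each sex). Smox, spermine oxidase, was lower in females by both of its called probes (−2.06, SE 0.15, adjusted p = 0.00131, and −2.25, SE 0.21, adjusted p = 0.00554), and Odc1, ornithine decarboxylase, gave −1.29 (SE 0.23, adjusted p = 0.0479). Socs2, a suppressor of growth hormone signalling, was higher in females by 3 probes, at 1.55, 1.65 and 1.67 (adjusted p = 0.00848 to 0.0172). Ak4, a mitochondrial adenylate kinase, was higher in females (1.95, SE 0.16, adjusted p = 0.00244). Irs2, an adaptor of the insulin receptor, was lower (−1.35, SE 0.18, adjusted p = 0.0189), as was Pfkfb3, a regulator of glycolysis (−1.14, SE 0.15, adjusted p = 0.0188).

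Of 11893 genes 203 differed between the sexes by at least 1 probe. Among the fixed lists, where the brightest probe stood for each gene, the counts were 2 of 21 biogenesis regulators, 2 of 22 denervation genes and 1 of 75 mitochondrial ribosomal proteins. There was also 1 each in the lists of the tricarboxylic acid cycle, glycolysis, immediate early genes, fibroblasts and Schwann cells, besides 2 of 3 sex-linked genes, and 0 in all other lists. By any probe both Hk2 and Pfkfb3 of the glycolysis list were called, as was Phgdh of the stress response list (0.71, SE 0.13, adjusted p = 0.0415). The list counts are thus stricter than the count of 203 genes. No test compared these counts with the share over all genes. Of the regulators, Esrra, a nuclear receptor of mitochondrial biogenesis, was lower in females (−0.81, SE 0.12, adjusted p = 0.0283) and Twnk, the mitochondrial DNA helicase, was higher (0.64, SE 0.11, adjusted p = 0.0386). Musk, a kinase of the neuromuscular junction in the denervation list, was lower in females (−0.82, SE 0.10, adjusted p = 0.0153). Outside the lists, the probe of Eif2s3x, the X-linked partner of Eif2s3y, gave −2.26 (SE 0.19, adjusted p = 0.00306). Whether that probe also reads Eif2s3y, which was far higher in males, was not tested, so a sex difference of Eif2s3x itself is uncertain. Abra, which lay higher in mutants by 0.65 without passing, was higher in females than in males by 0.96 (SE 0.11, adjusted p = 0.0118).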
